A study of Mus musculus with 20 samples.

How the data were processed

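Ribosome-protected fragments were sequenced from mouse embryonic stem cells (mESCs) with an alanine knock-in at the regulatory phosphorylation site of eIF2α (eIF2αA/A, KI) and from wild-type cells (eIF2α+/+, WT). eIF2α, encoded by Eif2s1, is the subunit of the initiation factor eIF2 whose phosphorylation lowers general initiation and raises translation of Atf4. Per the labels, each genotype was kept in LIF with the MEK and GSK3 inhibitors PD0325901 and CHIR99021 (LIF/2i) or in LIF without the inhibitors for 6 days. Lysates were digested with micrococcal nuclease (MNase, 3 replicates per group, 12 libraries) or with RNase I (2 replicates per group, 8 libraries). Per the labels' protocols, the medium was serum-free with KnockOut serum replacement and LIF at 1000 U/mL, and cycloheximide was used. Also per the labels' protocols, fragments of 25 to 40 nt from monosome fractions were cloned after rRNA depletion with linkers that carry molecular identifiers and were sequenced on a NovaSeq.

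The deposited table holds raw counts of footprints in coding sequences, with 1 Ensembl transcript for each of 22416 gene names and a column for each of 20 libraries. Per the submitters' processing notes, cutadapt 3.4, Bowtie 1.3.0 and UMI-tools 1.0.1 were used, and the counts were not normalized. The reference build behind the counts is not given in the sources used here, so no coordinates are printed. The file writes gene names in capitals, and 21755 were given mouse spelling while 661 were kept as written. No RNA-seq was used here, so a difference in footprints combines RNA level and translation, and no translational efficiency was computed. The amino acid change itself cannot be read from the counts, and the level of Eif2s1 does not check the genotype labels. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between samples as labelled. Molecular identifiers were used per the submitters' notes, and the spread between libraries, not counting error alone, set the errors.

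The counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The 12 MNase libraries were fitted together with a mean for each of 4 groups after filterByExpr and TMM normalization. Contrasts were tested with edgeR's quasi-likelihood test, with adjustment by Benjamini-Hochberg (BH) over all tested genes and a threshold of 0.05, all tests being two-sided. The 5 comparisons were KI against WT in each medium, LIF against LIF/2i in each genotype, and the genotype by medium interaction. The 8 RNase I libraries were fitted separately with the same contrasts. The effect of the nuclease was tested on replicates 1 and 2 of all 8 groups, 16 libraries, with genotype and medium as covariates. Levels are CPM, counts scaled by TMM-adjusted library totals, given as mean ± SD. Levels of Ddx3y and Eif2s3y in single libraries are per raw library total instead. Fold changes are log2 values with the SE of the fit. The fit tested 12806 genes with MNase and 12095 with RNase I, with a biological coefficient of variation of 0.210 and 0.218.

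Lists were tested with camera in limma on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with BH over the lists of a contrast, and with an estimated correlation and with fry as alternatives. The 32 lists, with 736 of 745 members found in the file, covered naive pluripotency, core pluripotency, formative and primed pluripotency, the integrated stress response (targets of ATF4 and CHOP), mRNAs with upstream reading frames that respond to eIF2α phosphorylation, and subunits of eIF2, eIF2B and the eIF2α kinases and phosphatases. They also covered the unfolded protein response (targets of ATF6 and XBP1), WNT/beta-catenin targets, MEK/ERK targets, the LIF/STAT3 pathway, cytosolic ribosomal proteins, other mRNAs with terminal oligopyrimidine tracts, cytosolic chaperones, cholesterol synthesis, glycolysis, mitochondrially encoded subunits, nuclear-encoded oxidative phosphorylation subunits, and lysosome and autophagy. The others were S phase, G2 and M phase, p53 targets, imprinted genes, DNA methylation machinery, replication-dependent histones, germline genes repressed by DNA methylation, sex-linked genes, and markers of other cell types. These markers were for the 2-cell-like state, primitive and extraembryonic endoderm, mesoderm and primitive streak, neuroectoderm, trophoblast, and fibroblasts and feeder cells. Counts of passing members are given from the adjustment over all genes and, where stated, adjusted over the list alone.

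For each comparison, genes were named among those with adjusted p under 0.05, a mean of at least 5 CPM and no overlap of log2 CPM between the groups compared (a condition not used for the interaction). From these came the 8 largest rises, the 8 largest falls and the 4 smallest adjusted p values, with Eif2s1 added, and from each list up to 3 members with the smallest p and any needed to describe it. The predicted genes Gm364 and Gm15262 met the rule and were passed over. A few other genes that met the rule are not reported here. The comparisons, tests, lists, naming rule and first set of alternatives were fixed before the data were examined. That set held other scaling factors, DESeq2, other filters, a replicate block, the compared groups alone, removal of abundant gene families, a test against a fold of 1.5, leaving out each library in turn, and both nucleases in one model. Alternatives chosen after the data were seen were leaving out KI replicate 1 or KI replicates 2 and 3, a replicate block within each genotype, and thinning of all MNase libraries to the smallest. The test of the difference of the genotype effect between nucleases, in the 16 libraries, was also chosen then, as were its replicate block of libraries with the same group and number and the comparison of MNase replicate 3 alone with RNase I.

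The pairing of libraries by replicate number was checked from residuals. Between KI libraries in LIF/2i and KI libraries in LIF with the same number, residuals correlated at 0.563, 0.315 and 0.393 across genes, all over the bound of 0.1 by which the numbers were taken as pairing the KI media, while the WT values were 0.015, 0.078 and 0.035. Only KI replicate 1 correlated best with its own number, since KI replicates 2 and 3 reached 0.367 and 0.404 with another number. In WT the Y-linked gene Ddx3y was lowest in replicate 2 in both media, and lower there with RNase I too, so WT numbers may also tie libraries. No libraries were duplicates, the lowest chi-square per degree of freedom within a group being 2.64. The pipeline was tested on simulated data with the design of KI against WT in LIF, in which 200 genes were changed. With MNase 11.9, 38.8 and 83.3% were recovered at 1.5-, 2- and 4-fold, with 5 false calls among 12551 genes. With RNase I 0, 17.9 and 65.2% were recovered, with 1 false call among 11671. No library was left out of the main tests. Where single libraries were left out, they are named by group and replicate number, such as WT LIF 3, with the adjusted p without that library in parentheses. With RNase I this leaves 1 library in a group, which is assumed to vary like the other groups. GC content and transcript length were not tested, since no genome sequence was used here.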

Results

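Footprints were counted in 20 libraries from KI and WT mESCs kept in LIF/2i or moved to LIF for 6 days. Each of the 4 groups of genotype and medium had 3 MNase and 2 RNase I libraries. The MNase libraries held from 2127850 to 5461210 counts in WT and from 6560173 to 8894080 in KI, so that depth and genotype did not overlap. The RNase I libraries held from 4011036 to 22916734 counts in WT and from 1965050 to 16359039 in KI. Between 14046 and 16036 genes were detected per library. The design asks how the knock-in at the eIF2α phosphorylation site changes ribosome occupancy in each medium, how each genotype responds to the removal of the inhibitors, and whether these responses differ.

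Eif2s1, which encodes eIF2α, was at 101 ± 11.2 CPM in WT and 158 ± 19.9 CPM in KI in LIF/2i (SD, n = 3). It was higher in KI by a log2 fold change of 0.65 (SE 0.13, edgeR adjusted p = 0.0040). In LIF the levels were 108 ± 8.17 and 133 ± 2.44 CPM, a difference of 0.30 (SE 0.13) that did not pass the test (edgeR adjusted p = 0.136). The MNase libraries separated by medium on the first principal component, with 42.3% of the variance, and by genotype on the second, with 22.5%. KI replicate 1 stood apart from KI replicates 2 and 3 on the third component, with 9.94% of the variance. Its positions were −44.4 and −45.5 in the 2 media, while the other 10 MNase libraries lay between −1.0 and 21.6. Spearman correlations between KI replicates 2 and 3 were 0.994 and 0.992 in the 2 media. Ddx3y, a Y-linked RNA helicase, was at 134, 18.9 and 161 CPM in WT replicates 1, 2 and 3 in LIF/2i and at 107, 29.3 and 112 CPM in LIF. In KI the Ddx3y levels of replicates 1, 2 and 3 were 65.4, 0.955 and 0.670 CPM in LIF/2i and 21.2, 1.52 and 4.16 CPM in LIF.

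**Figure D1:**
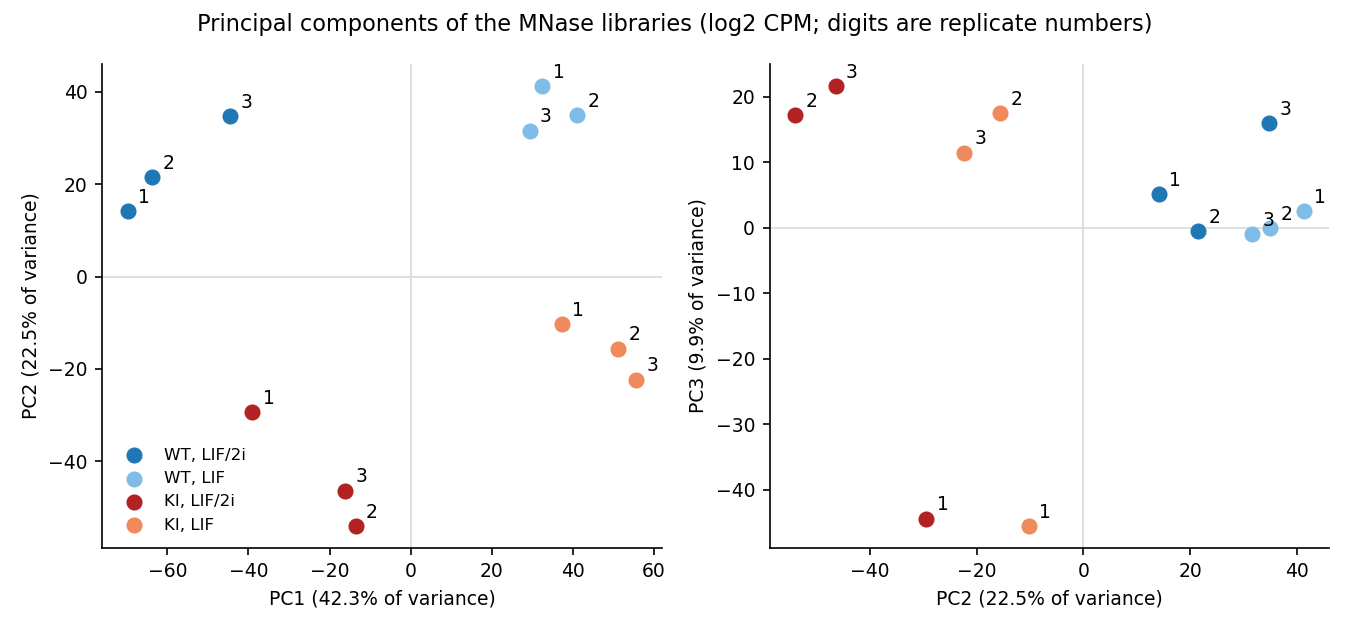
Principal components of log2 CPM in the 12 MNase libraries, PC1 (42.3% of variance) against PC2 (22.5%) on the left and PC2 against PC3 (9.9%) on the right, in component units, colored by group, with each point's replicate number. Media part on PC1, genotypes on PC2, and KI replicate 1 of both media lies alone at the low end of PC3.

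In LIF/2i, KI was compared with WT under full inhibitor culture. In both media, depth and any line, clone or batch that the labels do not give cannot be told apart from genotype. Footprints fell in KI on Myo7a, an unconventional myosin (log2 fold change −5.10, SE 0.35, n = 3 per group, edgeR adjusted p = 1.0e-05), and on Casr, the calcium-sensing receptor (−3.67, SE 0.28). They also fell on Naalad2, a peptidase (−3.47, SE 0.38), and on Sgpp1, a sphingosine-1-phosphate phosphatase (−2.71, SE 0.22). Slc16a3, a monocarboxylate transporter, fell by 3.87 (SE 0.67) and Cyp39a1, a sterol hydroxylase, by 3.76 (SE 0.46). Higher in KI were Cyp1a1, a target of the aryl hydrocarbon receptor (0.396 ± 0.174 CPM in WT, 40.0 ± 25.3 in KI), and the actin-binding gene Tagln (0.360 ± 0.315 and 32.1 ± 19.7). The same held for Plac8 (0.164 ± 0.284 and 5.93 ± 2.31), the myosin Myo1f (0.826 ± 0.599 and 20.7 ± 4.04) and Zfp629 (0.396 ± 0.174 and 7.13 ± 4.85). Rragb, a Rag GTPase of amino acid signalling to mTORC1, rose by 3.80 (SE 0.53) and the ferroxidase Heph by 3.75 (SE 0.77). For each of these genes the 3 KI and the 3 WT libraries did not overlap.

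Of the 13 mitochondrially encoded subunits, 10 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of −1.14 (camera adjusted p = 7.8e-07; adjusted p = 0.82 with an estimated correlation). The cytochrome oxidase subunit MT-CO2 went from 69.6 ± 11.9 to 4.56 ± 1.75 CPM, MT-CO3 from 82.9 ± 11.5 to 6.29 ± 2.31 and the ATP synthase subunit MT-ATP6 from 104 ± 15.2 to 10.8 ± 5.61. Among 20 glycolysis genes 8 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of −0.66 (camera adjusted p = 0.020; adjusted p = 0.82 with an estimated correlation). Pgk1 fell by 1.75 (SE 0.29) and Aldoc by 2.22 (SE 0.47), while the glucose transporter Slc2a3 rose by 0.57 (SE 0.11). Of 19 p53 targets 2 fell (0 adjusted over the list alone), with a list median of −0.64 (camera adjusted p = 0.018; 0.82 as adjusted p with an estimated correlation). Of 15 replication-dependent histones 5 fell, H2bc4 by 0.77 (SE 0.21) and the linker histone H1f4 by 0.68 (SE 0.14), with a median of −0.36 (camera adjusted p = 0.011; adjusted p = 0.82 with an estimated correlation). The histone median with RNase I was 0.18, of opposite sign. Of 18 fibroblast and feeder markers 5 rose and 0 fell, with a median of 1.29 (camera adjusted p = 0.011; adjusted p = 0.82 with an estimated correlation). S phase genes rose in 9 of 24 and fell in 1, with a median of 0.26 (camera adjusted p = 0.027; adjusted p = 0.82 with an estimated correlation). Pola1, Mcm6 and Prim1, of DNA polymerase alpha, the replicative helicase and primase, were higher by 0.81 (SE 0.16), 0.72 (SE 0.14) and 0.70 (SE 0.15). Of 49 nuclear-encoded oxidative phosphorylation subunits 13 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.036; adjusted p = 0.91 with an estimated correlation). With RNase I the medians were −0.02 for mitochondrially encoded subunits, 0.06 for nuclear-encoded ones and 0.07 for S phase genes, none of them called. In replicates 1 and 2 with a replicate block, no difference between nucleases passed camera for the last 2 lists (adjusted p = 0.387 and 0.089).

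Integrated stress response targets showed no shared direction in LIF/2i, with 7 higher and 5 lower of 34 and a median of 0.01 (camera adjusted p = 0.93). Of 19 mRNAs with responsive upstream reading frames, 3 were higher and 1 lower. Among 23 genes of eIF2, eIF2B and their regulators 9 were higher and 1 lower, the last being Eif2ak3, which encodes the kinase PERK, at −1.18 (SE 0.28). Core pluripotency genes were higher in 8 of 16 and lower in 1 (median 0.49, camera adjusted p = 0.051). The let-7 inhibitor Lin28a rose from 6.16 ± 0.443 to 60.2 ± 33.6 CPM. Of 20 naive genes 2 were higher and 0 lower. Formative and primed genes were higher in 2 of 20 and lower in 5, among them Pou3f1 at −1.36 and Lef1 at −1.62 (SE 0.29). Of 22 MEK/ERK targets 5 were higher and 1 lower, with the feedback inhibitor Spry4 at 1.32 ± 0.786 CPM in WT and 15.7 ± 3.93 in KI. Ccnd1, cyclin D1, was higher by 2.15 (SE 0.29). In the LIF/STAT3 pathway 1 of 13 was higher and 1 lower, the feedback inhibitor Socs3 at −0.96 (SE 0.20), and of 13 WNT targets 1 was higher and 2 lower. Counts higher and lower were 8 and 4 of 24 for the unfolded protein response, with the chaperone Hspa5 at 0.57 (SE 0.13), and 3 and 2 of 18 for cytosolic chaperones. They were 1 and 3 of 25 for cholesterol synthesis, and 3 and 1 of 32 for lysosome and autophagy. They were 11 and 14 of 78 for ribosomal proteins, 9 and 3 of 25 for other mRNAs with terminal oligopyrimidine tracts, and 7 and 1 of 24 for G2 and M phase. Higher and lower were 5 and 3 of 19 for imprinted genes, and 1 and 3 of 13 for the DNA methylation machinery. Germline genes repressed by DNA methylation were higher in 5 of 16 and lower in 2, the last including Dazl at −1.10. Markers of other cell types were higher and lower in 2 and 0 of 3 for the 2-cell-like state and 2 and 3 of 17 for primitive endoderm with Gata6 at −2.63 (SE 0.34). They were 1 and 0 of 5 for mesoderm, 0 and 0 of 9 for neuroectoderm, and 1 and 2 of 13 for trophoblast. Of 8 sex-linked genes tested 1 was higher and 0 lower. None of the lists described in these sentences passed camera in the main fit with all libraries, while germline genes passed with a replicate block. The core list passed without KI LIF 2 (0.033), KI LIF/2i 2 (0.025), KI LIF/2i 3 (0.022), WT LIF 3 (0.047) or WT LIF/2i 1 (0.036). Oligopyrimidine tracts passed without KI LIF/2i 2 (0.047), KI LIF/2i 3 (0.027) or WT LIF/2i 1 (0.014), and germline genes without KI LIF/2i 1 (0.0058). The median, mean and test differed in sign for the stress response, upstream reading frame, unfolded protein response, ribosomal protein, chaperone, cholesterol and trophoblast lists.

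Across 12806 genes 3250 passed edgeR's test in LIF/2i, 1773 higher and 1477 lower in KI. Thinning of all MNase libraries to the smallest gave 1611, and both nucleases fitted together gave 1874. With library totals alone, which shift the median of all genes by −0.10, 1322 were higher and 1935 lower. The count was 1574 without KI LIF/2i replicate 2 and 2065 without KI LIF/2i replicate 3. Without KI replicate 1 in both media it was 4949, and the glycolysis, oxidative phosphorylation and S phase calls were lost and that of germline genes was gained (0.013). Those calls also rested on single libraries, the glycolysis adjusted p being 0.115 without WT LIF/2i replicate 3. Without that library and without KI LIF/2i replicate 1 in turn, the adjusted p was 0.323 and 0.338 for oxidative phosphorylation and 0.110 and 0.149 for S phase.

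In LIF, the same comparison shows how KI and WT differed once the inhibitors were gone. Targets of ATF4 and CHOP were lower in KI as a group. Of 34 such genes 20 fell and 0 rose (25 and 0 adjusted over the list alone), with a median of −1.11 (camera adjusted p = 8.2e-13; adjusted p = 0.19 with an estimated correlation). The serine synthesis enzyme Psat1 fell from 402 ± 74.9 to 180 ± 12.8 CPM (log2 −1.16, SE 0.14, n = 3 per group, edgeR adjusted p = 0.0011), and Phgdh of the same pathway fell by 1.57. Asparagine synthetase, Asns, fell by 1.43 (SE 0.20), and the pseudokinase Trib3 by 1.70 (SE 0.28). Larger falls were those of the CHOP gene Ddit3 by 2.08 (SE 0.39), the stress protein Nupr1 by 2.85 (SE 0.41) and the glutathione-degrading enzyme Chac1 by 3.41 (SE 0.45). The tRNA synthetases Nars at −0.81 (SE 0.12) and Aars at −0.45 were lower as well. Atf4 itself fell from 244 ± 48.7 to 112 ± 26.3 CPM (log2 −1.12, SE 0.19, edgeR adjusted p = 0.0031) and Atf5 by 1.94 (SE 0.32). Their list of mRNAs with upstream reading frames had 4 lower and 0 higher of 19 and did not pass (median −0.27, camera adjusted p = 0.097).

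**Figure D2:**
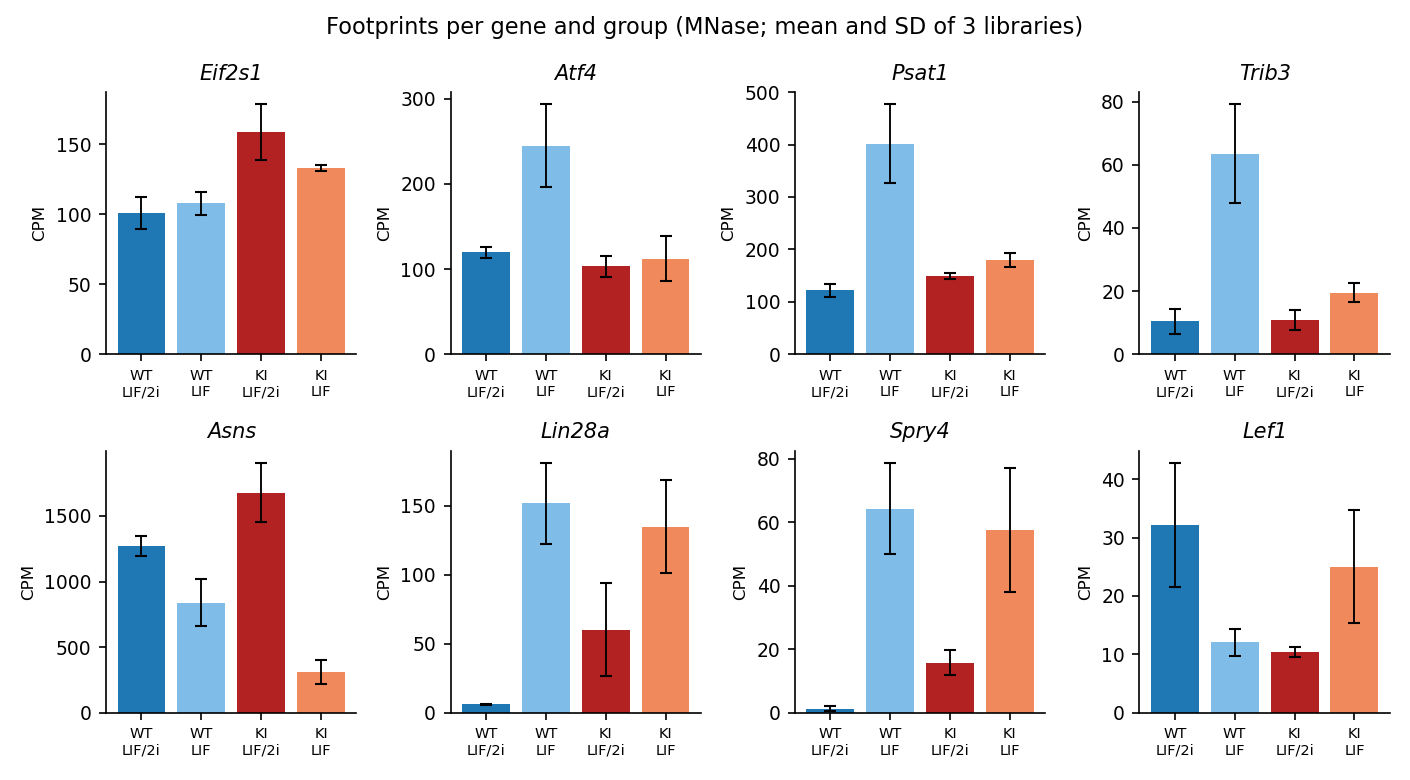
Footprint level in CPM (mean of 3 MNase libraries, error bars SD) of 8 genes in WT and KI cells in LIF/2i and LIF, with axes from 0. Psat1 stood at 402 CPM in WT LIF and at 180 CPM in KI LIF, and Lin28a and Spry4 were lowest in WT LIF/2i at 6.16 and 1.32 CPM.

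Endoderm and trophoblast markers moved with the stress response genes in LIF. Of 17 primitive and extraembryonic endoderm markers 9 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of −1.19 (camera adjusted p = 4.3e-06, and adjusted p = 0.034 with an estimated correlation). They included the transcription factors Gata6 at −2.18 (SE 0.30) and Sox17 at −2.74 (SE 0.46), the laminin Lama1 at −1.58 (SE 0.21) and the receptor Cubn, from 45.4 ± 14.4 to 3.39 ± 2.86 CPM. Of 13 trophoblast markers 6 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of −1.49 (camera adjusted p = 5.2e-05; adjusted p = 0.41 with an estimated correlation). Gata3 went from 41.4 ± 3.47 to 3.07 ± 1.90 CPM, and the homeobox genes Rhox6 and Rhox9 fell by 2.56 (SE 0.38) and 2.49 (SE 0.34). Formative and primed genes were higher, in 7 of 20 with 0 lower (11 and 1 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.0034; adjusted p = 0.41 with an estimated correlation). The de novo methyltransferase Dnmt3a rose by 0.95 (SE 0.27), Nodal by 0.94 (SE 0.14), Lefty1 by 1.65 (SE 0.41), Lef1 by 1.03 (SE 0.30) and Sox3 by 1.19 (SE 0.28). Of 20 naive genes 3 were lower, among them Nanog at −0.76 (SE 0.15) and Klf5 at −1.02 (SE 0.20), and 1 was higher, without a call for the list. Mitochondrially encoded subunits fell in 6 of 13 and rose in 0 (9 and 0 adjusted over the list alone), with a median of −0.77 (camera adjusted p = 1.8e-04; adjusted p = 0.71 with an estimated correlation). Ribosomal protein genes fell in 11 of 78 and rose in 2 (18 and 2 adjusted over the list alone), with a median of −0.21 (camera adjusted p = 0.0034; adjusted p = 0.75 with an estimated correlation). With RNase I the medians of these last lists were 0.70 and 0.41, of opposite sign.

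Single genes with the largest falls in LIF included Myo7a at −3.47 (SE 0.31), Ubap1l at −3.61 (SE 0.37) and Pramel7 (5.92 ± 0.813 to 0.558 ± 0.730 CPM). Y-linked Eif2s3y was lower too, at −3.96 (SE 1.19). It was at 59.7, 25.4 and 89.0 CPM in WT LIF replicates 1, 2 and 3 and at 9.12, 0.762 and 1.12 in KI LIF. As with Ddx3y, the level was lowest in KI replicates 2 and 3, so a difference between cultures cannot be told from the knock-in. The placental homeobox gene Rhox5 fell by 2.00 (SE 0.20) and the semaphorin Sema5a by 2.25 (SE 0.23), both with an edgeR adjusted p of 6.6e-04. Among the largest rises were Ccnd1 at 2.17 (SE 0.28), the chromatin remodeller Smarca1 at 2.21 (SE 0.36) and Rragb at 2.09 (SE 0.44). Others were the guidance cue Ntn1 at 2.62 (SE 0.80), Nlrp4c at 2.39 (SE 0.54) and Fam171b at 2.04 (SE 0.41). In all, 1718 genes passed, 943 higher and 775 lower in KI, against 838 and 887 with library totals alone, so that the larger side depended on the scaling. Thinning of all MNase libraries to the smallest gave 940. The median, mean and test differed in sign for the WNT, oligopyrimidine tract, chaperone, cholesterol, imprinted, fibroblast and germline lists, none of them called. The count was 718, 939 and 894 without WT LIF replicates 1, 2 and 3, and 1140 and 771 without KI LIF replicates 2 and 3. Without KI replicate 1 in both media 3384 genes passed, the formative call was lost and that of p53 targets was gained (3.0e-05). The ribosomal protein adjusted p was 0.109 without WT LIF replicate 3, and the formative adjusted p was 0.091 without WT LIF replicate 1. The p53 list, which was not called with all libraries, had an adjusted p of 1.2e-04 without KI LIF replicate 1. Calls were also gained for upstream reading frames without KI LIF 3 (0.019) and WT LIF 2 (0.023), naive genes without WT LIF 2 (0.048) and S phase without KI LIF 2 (0.043). Without KI LIF 2, KI LIF 3, WT LIF 1, WT LIF 2 and WT LIF 3 in turn, calls were lost for Eif2s3y (0.1253, 0.152, 0.102, 0.060 and 0.130) and Ntn1 (0.072, 0.139, 0.124, 0.136 and 0.114). Eif2s3y also lost its call without WT LIF/2i 1 (0.061) and WT LIF/2i 3 (0.052), Ntn1 without WT LIF/2i 1 (0.058), and Nlrp4c without WT LIF 1 (0.055) and WT LIF 2 (0.051). Cubn lost its call with DESeq2.

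Genotype effects in the 2 media correlated across genes at a Pearson r of 0.525 and a Spearman rho of 0.572, genes not being independent replicates. The 2 effects share no library, but KI libraries shared deviations between media (residual correlations of 0.563, 0.315 and 0.393 by number). Only replicate 1 was tied by its number, since replicates 2 and 3 reached 0.367 and 0.404 with another number. The effects are thus not independent, which the expected counts below leave out. Of the genes that passed in both, 659 were higher in KI in both and 392 lower in both, against 130.6 and 89.4 with independent calls, and 16 moved in opposite directions.

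In WT cells, the comparison of LIF with LIF/2i shows the response to removal of the inhibitors. Naive genes fell, in 13 of 20 with 0 higher (14 and 0 adjusted over the list alone), with a median of −0.70 (camera adjusted p = 4.0e-06; adjusted p = 0.20 with an estimated correlation). Prdm14 fell by 1.96 (SE 0.20), Tfcp2l1 by 1.80 (SE 0.21), Klf2 by 1.27 (SE 0.15), Nanog by 0.49 (SE 0.15) and Zfp42 by 0.73, while the core factor Pou5f1 was at 828 and 799 CPM. MEK/ERK targets rose in 10 of 22 and fell in 2 (11 and 2 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 2.5e-04; adjusted p = 0.20 with an estimated correlation). Spry4 went from 1.32 ± 0.786 to 64.2 ± 14.4 CPM, the phosphatase Dusp6 rose by 3.47 (SE 0.28) and the early-response factor Egr1 by 3.33. WNT targets fell in 6 of 13 and rose in 1 (7 and 1 adjusted over the list alone), with a median of −0.56 (camera adjusted p = 0.046; adjusted p = 0.27 with an estimated correlation). Axin2 fell by 2.05 (SE 0.37) and Sp5 from 28.7 ± 24.2 to 0.785 ± 0.991 CPM. Integrated stress response targets rose in 24 of 34 and fell in 1 (26 and 1 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 3.7e-09; adjusted p = 0.20 with an estimated correlation). Psat1 rose by 1.71 (SE 0.14), Trib3 by 2.59 (SE 0.31), Chac1 by 2.76 (SE 0.46), Atf4 by 1.03 (SE 0.19) and Atf5 by 2.33 (SE 0.34). Asns, the member that fell, was lower by 0.59 (SE 0.19). The upstream reading frame list had 3 higher and 0 lower of 19 (3 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.044; adjusted p = 0.48 with an estimated correlation).

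Markers of other cell types rose in the same WT comparison. Fibroblast and feeder markers rose in 13 of 18 and fell in 1 (14 and 2 adjusted over the list alone), with a median of 3.41 (camera adjusted p = 1.0e-06; adjusted p = 0.21 with an estimated correlation). The collagen Col1a2 went from 0.416 ± 0.255 to 133 ± 185 CPM and Tagln from 0.360 ± 0.315 to 78.6 ± 74.8. WT LIF replicate 2 carried much of these levels, with Col1a2 at 39.2, 346 and 13.7 CPM and Tagln at 32.9, 165 and 38.2 CPM in replicates 1, 2 and 3. It was the highest of the 3 for 14 of the 18 markers, and without it the list median was 2.50 (camera adjusted p = 3.0e-07). Trophoblast markers rose in 10 of 13 and fell in 1 (11 and 1 adjusted over the list alone), with a median of 3.31 (camera adjusted p = 3.1e-05; adjusted p = 0.21 with an estimated correlation). Primitive endoderm markers rose in 7 of 17 and fell in 1 (12 and 1 adjusted over the list alone), with a median of 1.65 (camera adjusted p = 1.6e-04; adjusted p = 0.11 with an estimated correlation). Neuroectoderm markers rose in 2 of 9 (2 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.044; adjusted p = 0.20 with an estimated correlation). Imprinted genes rose in 10 of 19 and fell in 2 (10 and 3 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 0.018; adjusted p = 0.23 with an estimated correlation). Mest rose by 2.66, while the zinc-finger gene Plagl1 fell by 4.17 (SE 0.32). Formative genes were higher in 8 of 20 and lower in 5 and did not pass (camera adjusted p = 0.144). Otx2 was at 2.90 (SE 0.48), Dnmt3a at 1.70 (SE 0.28) and Pou3f1 at 2.17 (SE 0.34), Nodal at −1.09 and Lefty2 at −3.64.

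Of the single genes, the GTPase gene Eras rose by 3.41 (SE 0.19, edgeR adjusted p = 1.5e-06), and the integrin Itga3 by 2.47 (SE 0.16). The transferrin receptor Tfrc fell by 1.76 (SE 0.11, edgeR adjusted p = 2.1e-06). From near the detection limit rose Car4, a carbonic anhydrase (0.452 ± 0.549 to 66.9 ± 43.6 CPM), and the ligand gene Bmp4 (0.318 ± 0.360 to 24.3 ± 8.55). So did Col12a1 (0.282 ± 0.254 to 15.9 ± 10.5) and Vgf (0.555 ± 0.758 to 22.2 ± 23.5), and Col1a1 went from 2.55 ± 0.675 to 126 ± 143 (63.9, 290 and 25.1 CPM in LIF replicates 1, 2 and 3). Casr fell from 36.0 ± 5.73 to 0.924 ± 0.412 CPM, the cation channel Trpm1 from 18.7 ± 12.8 to 0.456 ± 0.790, and Srarp from 28.0 ± 22.3 to 0.541 ± 0.242. Falls were also seen for Dmgdh from 13.4 ± 5.36 to 0.328 ± 0.286, Stk33 (log2 −4.69, SE 0.67), Ppp1r14d from 29.4 ± 23.6 to 0.959 ± 0.110 and A2m from 42.5 ± 31.6 to 1.97 ± 0.436. Eif2s1 differed by 0.10 (SE 0.13, edgeR adjusted p = 0.65). A total of 2690 genes passed, 1279 higher and 1411 lower in LIF. The larger side depended on the scaling, with 1477 higher and 1223 lower with upper-quartile factors and 1406 and 1265 with library totals alone. The count was 1654 without WT LIF/2i replicate 1, 1750 without WT LIF replicate 2 and 1737 without WT LIF replicate 3. The call of the WNT list was lost with a replicate block and without WT LIF/2i 1 (0.195), WT LIF/2i 2 (0.060), WT LIF 1 (0.067), KI LIF/2i 1 (0.052), KI LIF/2i 3 (0.052), KI LIF 2 (0.054) or KI LIF 3 (0.052). That of the upstream reading frame list was lost without WT LIF/2i replicates 2 (0.060) and 3 (0.070) and WT LIF replicates 1 (0.062) and 3 (0.081). That of neuroectoderm was lost without WT LIF/2i replicates 2 (0.069) and 3 (0.062) and WT LIF replicate 2 (0.070). A2m lost its call without WT LIF 1 (0.070), WT LIF 2 (0.084), WT LIF 3 (0.077) or WT LIF/2i 3 (0.074). List calls were gained for cholesterol without WT LIF/2i 3 (0.032), ribosomal proteins without WT LIF 1 (0.032) and WT LIF/2i 1 (0.026), and formative genes without WT LIF 1 (0.041) and WT LIF/2i 1 (0.033). They were gained for glycolysis without KI LIF/2i 1 (0.046) and WT LIF/2i 2 (3.8e-04), and for lysosome without WT LIF/2i 1 (0.034). The block within each genotype also gave a glycolysis call (0.049). Median, mean and test differed in sign for the mitochondrial and mesoderm lists, neither of them called.

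In KI cells, the same medium comparison shows the response with the alanine knock-in at the eIF2α phosphorylation site. Naive genes fell in 16 of 20 and rose in 1 (17 and 1 adjusted over the list alone), with a median of −1.03 (camera adjusted p = 3.6e-09; adjusted p = 0.10 with an estimated correlation). Tfcp2l1 fell by 2.48 (SE 0.21), Prdm14 by 1.85 (SE 0.19), Nanog by 1.15 (SE 0.15), Esrrb by 0.77 (SE 0.14) and Klf5 by 1.00 (SE 0.19). Formative and primed genes rose in 13 of 20 and fell in 3 (13 and 3 adjusted over the list alone), with a median of 1.65 (camera adjusted p = 8.1e-06; adjusted p = 0.10 with an estimated correlation). Pou3f1 rose by 4.41 (SE 0.35), Otx2 by 2.72 (SE 0.46) and Dnmt3a by 2.39 (SE 0.28). Integrated stress response targets had 2 higher and 3 lower of 34, a median of 0.02 and a camera adjusted p of 0.92. Psat1 was at 0.27 and Atf4 at 0.12, neither passing, and Asns fell by 2.43 (SE 0.20). MEK/ERK targets rose in 7 of 22 and fell in 2 (8 and 3 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.011; adjusted p = 0.35 with an estimated correlation). Lysosome and autophagy genes fell in 14 of 32 and rose in 1 (15 and 2 adjusted over the list alone), with a median of −0.41 (camera adjusted p = 7.3e-04; adjusted p = 0.13 with an estimated correlation). They included the hydrolases Glb1 at −1.21 and Ctsa at −1.18 (SE 0.14). Imprinted genes rose in 8 of 19 and fell in 1 (12 and 2 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 0.011; adjusted p = 0.30 with an estimated correlation).

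In KI, neuroectoderm markers rose in 4 of 9 genes tested (5 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 0.0028; adjusted p = 0.10 with an estimated correlation). Fibroblast and feeder markers rose in 9 of 18 and fell in 1 (10 and 1 adjusted over the list alone), with a median of 1.57 (camera adjusted p = 0.0011; adjusted p = 0.50 with an estimated correlation). Trophoblast markers rose in 1 of 13 and fell in 1 (4 and 1 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.037; adjusted p = 0.71 with an estimated correlation). Mitochondrially encoded subunits rose in 3 of 13 (3 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.013; adjusted p = 0.71 with an estimated correlation). MT-CO2 rose by 2.16, MT-CO3 by 1.98 and MT-ATP6 by 1.98. Nuclear-encoded oxidative phosphorylation subunits fell in 6 of 49 and rose in 0 (6 and 0 adjusted over the list alone), with a median of −0.17 (camera adjusted p = 0.011; adjusted p = 0.71 with an estimated correlation). S phase genes fell in 6 of 24 and rose in 1 (6 and 2 adjusted over the list alone), with a median of −0.20 (camera adjusted p = 0.037; adjusted p = 0.71 with an estimated correlation). Single genes that rose from near the detection limit were Car4 (0.486 ± 0.470 to 61.7 ± 33.2 CPM), and Hand1 (0.047 ± 0.0815 to 7.62 ± 3.05). Others were the neuronal transcription factors Neurod1 (0.289 ± 0.165 to 14.6 ± 14.1) and Insm1 (0.375 ± 0.0883 to 7.51 ± 1.21). Higher too were Wt1 (0.816 ± 0.779 to 26.4 ± 12.1), Vgf (log2 4.53, SE 0.76) and Col1a2 (1.05 ± 0.765 to 40.2 ± 10.9). The channel subunit Cacng7 rose by 3.03 (SE 0.22). Plagl1 fell by 4.12 (SE 0.31), and Gsto1, a glutathione transferase, by 1.79 (SE 0.12, edgeR adjusted p = 1.1e-05). Falls to near the detection limit were those of the glutamate transporter Slc1a1 from 21.9 ± 7.14 to 0.868 ± 0.626 CPM and the collagen receptor Ddr2 from 8.38 ± 0.755 to 0.436 ± 0.136. Trpm1 (9.94 ± 6.30 to 0.193 ± 0.334 CPM), Cyp1a1 (40.0 ± 25.3 to 1.17 ± 0.730), Srarp (log2 −5.01, SE 0.79), Dmgdh (9.46 ± 5.32 to 0.376 ± 0.210) and Sh2d4b (12.6 ± 6.61 to 0.564 ± 0.315) fell as well. Eif2s1 differed by −0.25 (SE 0.13, edgeR adjusted p = 0.19).

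In KI, 2395 genes passed between media, 1072 higher and 1323 lower in LIF. With library totals alone, which shift the median of all genes by 0.10, 1423 were higher and 1023 lower, and with upper-quartile factors 1286 and 1111. With a replicate block within each genotype 3595 genes passed. The count was 1507 without KI LIF/2i replicate 2 and 1478 without KI LIF replicate 3. Calls were lost for oxidative phosphorylation without KI LIF/2i replicate 1 (0.193) and KI LIF replicate 3 (0.113), and for S phase without KI LIF/2i replicate 1 (0.172) and KI LIF replicates 2 (0.225) and 3 (0.107). The trophoblast call was lost without KI LIF/2i 1 (0.264), KI LIF 2 (0.103), KI LIF 3 (0.110), WT LIF 1 (0.087), WT LIF/2i 1 (0.082), WT LIF/2i 2 (0.055) or WT LIF/2i 3 (0.124), without KI replicate 1 in both media and with a replicate block. The block within each genotype ended the S phase call as well. Calls were gained without KI LIF 1 for cholesterol (0.032) and the unfolded protein response (0.024). Median, mean and test differed in sign for the stress response, ribosomal protein, glycolysis and mesoderm lists, none of them called. Medium effects in WT and KI correlated across genes at a Pearson r of 0.709 and a Spearman rho of 0.613. Among genes passing in both genotypes, 540 rose in both and 753 fell in both, against 107 and 146 with independent calls, and 15 moved in opposite directions.

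**Figure D3:**
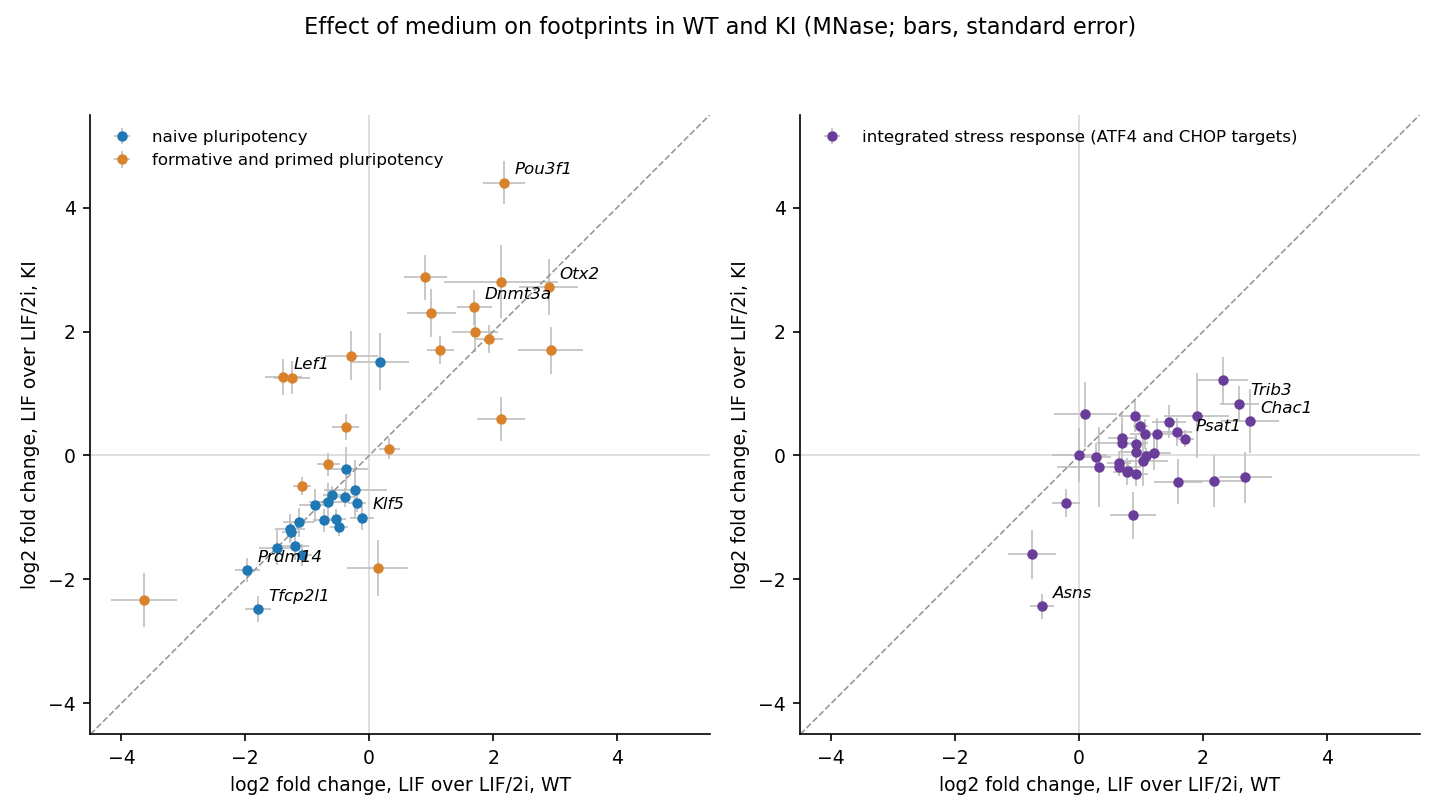
Log2 fold change of LIF over LIF/2i in WT (x axis) against KI (y axis), MNase, n = 3 libraries per group, error bars SE, for naive (blue) and formative (orange) genes on the left and integrated stress response targets on the right, with the line of equal effects dashed. Stress response targets had a median of 0.92 in WT and 0.02 in KI.

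The interaction tests whether the medium effect differed between genotypes. It was negative for the stress response list, whose median interaction was −0.97 (camera adjusted p = 2.9e-16; adjusted p = 0.10 with an estimated correlation). Of 34 genes 0 were higher and 4 lower (0 and 18 adjusted over the list alone). Those 4 genes were Asns at −1.84 (SE 0.27, edgeR adjusted p = 0.012), Psat1 at −1.45 (SE 0.20, edgeR adjusted p = 0.0086), Nars at −1.09 (SE 0.16, 0.013) and Aars at −1.04 (SE 0.17, 0.021). Atf4 at −0.91 and Atf5 at −2.22 did not pass (edgeR adjusted p = 0.18 and 0.064). Spry4 at −3.75 (SE 0.55), Lin28a at −3.46 (SE 0.49) and Eras at −1.93 (SE 0.25) rose less in KI, where they started from higher levels in LIF/2i. Lef1 at 2.65 (SE 0.42) and Sox3 at 2.50 (SE 0.39) fell in WT and rose in KI. MT-CO2 at 2.81 (SE 0.44) and MT-CO3 at 2.66 (SE 0.34), the histone genes H2ac18 at 2.52 and HIST1H4M at 2.35, Abhd8 at 2.15 and Ccdc136 at 1.76 were also positive. Rhox9 at −3.09 (SE 0.54), Rpl7 at −3.02, the tetraspanin Cd63 at −2.79, and Rplp0 at −2.06 were negative. So were Eif4a3 of the exon junction complex at −2.04, the prostaglandin synthase Ptges at −1.96 and Gsto1 at −1.47 (SE 0.17). Eif2s1 at −0.35 (SE 0.18) did not pass (edgeR adjusted p = 0.47). Histone, ribosomal protein and Rhox genes have close paralogs, so that shared reads leave their values uncertain.

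Endoderm markers had a median interaction of −0.61 (camera adjusted p = 5.2e-05; adjusted p = 0.070 with an estimated correlation). The medians were −2.04 for trophoblast (camera adjusted p = 3.0e-04; adjusted p = 0.43 with an estimated correlation) and −1.57 for fibroblasts and feeder cells (3.3e-04; 0.50, in the same order). They were −2.17 for the 2-cell-like state (0.013; 0.42) and 0.64 for formative genes (3.2e-04; 0.28). The 2-cell-like value rests on 3 tested members of 22, among them Arg2 at 12.3 ± 12.3 CPM in KI in LIF/2i. With an estimated-correlation adjusted p of 0.50 in each case, the camera call was negative for the upstream reading frame list (median −0.40, adjusted p = 0.031), MEK/ERK targets (−0.31, 0.027), and ribosomal proteins (−0.21, 0.0064). It was also negative for other mRNAs with oligopyrimidine tracts (−0.17, 0.024), nuclear-encoded oxidative phosphorylation (−0.27, 4.1e-05) and germline genes (−0.84, 0.032). It was positive, with the same adjusted p of 0.50, for glycolysis (0.32, 0.031), mitochondrially encoded subunits (0.40, 6.3e-04) and histones (0.30, 0.043). Median, mean and test differed in sign for the unfolded protein response, chaperone, mesoderm and neuroectoderm lists, none of them called.

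Of 12806 genes 43 passed the interaction test, 13 positive and 30 negative, against 1568 at an unadjusted p under 0.05. The count was 20 and 27 without WT LIF/2i replicates 1 and 3, and 10, 28 and 16 without WT LIF replicates 1, 2 and 3. It was 148 and 22 without KI LIF/2i replicates 1 and 2, and 95 and 23 without KI LIF replicates 1 and 2. It was 437 without KI replicate 1 in both media, 218 with DESeq2 and 218 with a replicate block within each genotype. Of the list calls, ribosomal proteins were lost without WT LIF 3 (0.061) and WT LIF/2i 3 (0.144), upstream reading frames without KI LIF 1 (0.168), KI LIF/2i 2 (0.053), WT LIF 1 (0.062) and WT LIF 3 (0.062), and MEK/ERK targets without KI LIF 1 (0.132) and KI LIF/2i 2 (0.068). Oligopyrimidine tracts were lost without KI LIF 2 (0.051), KI LIF/2i 1 (0.074), WT LIF 3 (0.061) and WT LIF/2i 3 (0.197), and the 2-cell-like state without KI LIF/2i 1 (0.059). Glycolysis was lost without KI LIF 1 (0.096), KI LIF/2i 2 (0.060), KI LIF/2i 3 (0.053), WT LIF 3 (0.051) and WT LIF/2i 3 (0.306). Germline genes were lost without KI LIF 1 (0.077), KI LIF/2i 2 and 3 (0.140 each), WT LIF 3 (0.098) and WT LIF/2i 1 (0.065). Histones were lost without KI LIF 1 (0.168), KI LIF 2 (0.050), KI LIF/2i 2 (0.169), KI LIF/2i 3 (0.140), WT LIF 1 (0.060), WT LIF 2 (0.110), WT LIF/2i 1 (0.065) and WT LIF/2i 3 (0.126). Without KI replicate 1 in both media the upstream reading frame, MEK/ERK, oligopyrimidine tract and glycolysis calls were lost, and with the block within each genotype those of MEK/ERK targets, oligopyrimidine tracts and histones, while p53 targets passed (0.046). Calls were gained for core genes without KI LIF 1 (0.027), KI LIF/2i 3 (0.035) and WT LIF 2 (0.014), and naive genes without WT LIF 2 (0.021) and WT LIF/2i 2 (0.044). For p53 targets they were gained without KI LIF 2 (0.0091), KI LIF 3 (0.0095), KI LIF/2i 1 (0.022) and WT LIF 2 (0.036). Mesoderm passed without WT LIF/2i 1 (0.039), S phase without KI LIF 1 (0.029) and WNT targets without WT LIF/2i 3 (0.0080).

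Single gene calls of the interaction also rested on single libraries. Lef1 lost its call without WT LIF 1 (0.064) and WT LIF 2 (0.053), MT-CO2 without WT LIF 1 (0.057) and WT LIF 3 (0.055), Sox3 without WT LIF 1 (0.051) and WT LIF 3 (0.067), and Ptges without WT LIF 1 (0.051). H2ac18 lost it without KI LIF 2 (0.059), WT LIF 1 (0.059), WT LIF 2 (0.058) and WT LIF/2i 1 (0.053). Rpl7 lost it without KI LIF 3 (0.064), KI LIF/2i 2 (0.071), WT LIF 1 (0.064), WT LIF 3 (0.080), WT LIF/2i 2 (0.053) and WT LIF/2i 3 (0.056). Without each of at least 8 libraries, calls were lost for Rhox9 (adjusted p from 0.072 to 0.097 over 8 libraries), Abhd8 (0.056 to 0.143 over 9), Ccdc136 (0.055 to 0.112 over 9) and HIST1H4M (0.055 to 0.097 over 10). The call was kept for Abhd8 and Ccdc136 only without KI LIF 1, KI LIF/2i 1 or KI LIF/2i 3, for HIST1H4M only without KI LIF 1 or KI LIF/2i 1, and for Rhox9 only without KI LIF 1, KI LIF 3, KI LIF/2i 1 or WT LIF/2i 2.

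The RNase I libraries give the comparisons with another nuclease. Across genes, replicate 1 minus replicate 2 correlated between nucleases at 0.735 and 0.673 in KI and 0.590 and 0.502 in WT, in LIF/2i and LIF, so that libraries of the same number shared their deviations and are not separate samples in what follows. The direction of the stress response in LIF was shared, with a median of −0.98 for KI against WT (camera adjusted p = 1.6e-12; adjusted p = 0.18 with an estimated correlation). Endoderm was at −1.86 and trophoblast at −1.53 (0.18 and 0.51 with an estimated correlation), and the median interaction of the stress response was −0.77 (0.20). Of genes called with MNase and tested with both, the same sign was found with RNase I for 2493 of 3124 in LIF/2i and 1566 of 1674 in LIF between genotypes. It was found for 2567 of 2587 between media in WT, 2174 of 2292 between media in KI and 37 of 42 for the interaction. Independent signs would give 1567, 834, 1291, 1151 and 21.6 in the order of the comparisons. Pearson correlations across 12046 genes were 0.615, 0.680, 0.913, 0.804 and 0.482 in that order. MNase replicate 3 alone, whose number no RNase I library has, correlated with RNase I at 0.467, 0.539, 0.727, 0.743 and 0.264. KI replicate 3 was close to KI replicate 2 with MNase (Spearman 0.994 and 0.992), so for KI it may not be a separate sample either. With 2 libraries per group, 28 genes passed edgeR's test between genotypes in LIF/2i (1554 unadjusted, 272 with DESeq2), and 14 in LIF (1612 unadjusted, 196 with DESeq2). Passing were 1649 between media in WT, 418 between media in KI (827 with DESeq2), and 0 for the interaction (645 unadjusted, 26 with DESeq2). The 28 ranged from 0 to 102 with 1 library left out. It was 0 without WT LIF/2i replicate 1 or 2, 8 and 7 without WT LIF replicates 1 and 2, 102 and 79 without KI LIF/2i replicates 1 and 2, and 7 without KI LIF replicate 1. The 14 became 3 without WT LIF/2i replicate 1 or 2, 0 without WT LIF or KI LIF replicate 1 or 2, and 45 and 44 without KI LIF/2i replicates 1 and 2. The replicate block gave 50 and 27. With RNase I alone the following named calls were lost in LIF/2i between genotypes, given with the RNase I fold change: Tagln (2.76), Plac8 (3.69), Zfp629 (4.76), Rragb (1.89), Heph (2.15), Slc16a3 (−2.59), Cyp39a1 (−1.90) and Eif2s1 (0.43). MT-CO2 (−0.57), MT-CO3 (−0.54) and MT-ATP6 (−0.02) lost their calls too and were nearer 0. Cyp1a1 was not among the genes tested with RNase I, so neither its genotype nor its medium call could be compared. The calls lost in other comparisons follow. In LIF they were Ntn1 (2.78), Nlrp4c (2.65), Smarca1 (1.45), Ccnd1 (2.52), Rragb (1.49), Fam171b (1.87), Gata3 (−2.74), Ubap1l (−3.18), Pramel7 (−4.01), Myo7a (−2.49), Chac1 (−3.29) and Eif2s3y (−2.53). Between media A2m (−4.04) lost its call in WT and Col1a2 (6.71), Vgf (4.05), Trpm1 (−2.92), Dmgdh (−3.73), Ddr2 (−3.09) and Gsto1 (−0.99) in KI, and all 18 named interaction calls were lost. RNase I interactions were 3.94 for Lef1, −3.35 for Lin28a, −3.69 for Rhox9, −2.20 for Eras, −2.49 for Spry4, 1.78 for Ccdc136 and −1.64 for Ptges. They were smaller for Sox3 (0.82), Abhd8 (1.08), MT-CO2 (0.66), MT-CO3 (0.51), Cd63 (−0.79) and Gsto1 (−0.80), and near 0 for H2ac18 (0.10), Eif4a3 (−0.13) and Rplp0 (−0.33). HIST1H4M at −0.34 and Rpl7 at 0.35 were of opposite sign.

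Mitochondrially encoded subunits had a median of −1.14 with MNase and −0.02 with RNase I in LIF/2i, and of −0.77 and 0.70 in LIF. In replicates 1 and 2 of both nucleases the genotype effect with MNase minus that with RNase I had a median of −1.07 in LIF/2i (camera adjusted p = 5.0e-09) and −1.50 in LIF (camera adjusted p = 8.4e-17). With an estimated correlation neither passed, at an adjusted p of 0.634 and 0.263. In the same libraries edgeR called 0 single genes in either medium (1118 and 372 unadjusted) without a replicate block. With libraries of the same group and number as a block it called 1950 in LIF/2i and 94 in LIF, among them 12 and 9 of the 13 mitochondrially encoded genes. The mitochondrial medians with the block were −1.001 and −1.48 (camera adjusted p = 7.7e-08 and 3.2e-14; 0.400 and 0.535 with an estimated correlation). On average over the groups, with genotype and medium as covariates, 4080 of 12732 genes differed between nucleases, 1998 higher and 2082 lower with RNase I. With the block 6001 differed. Higher with RNase I were Rpl19 at 3.13 (SE 0.21), Mrps36 at 3.07 (SE 0.18), Hnrnpa3 at 2.99 (SE 0.20), Sumo2 at 2.60 (SE 0.20) and Cox7c at 2.41 (SE 0.16). Lower were Tmem265 at −5.46 (SE 0.50), Map3k10 at −3.28 (SE 0.30), the ferritin genes Ftl1 at −2.89 (SE 0.35) and Fth1 at −2.43 (SE 0.23), and Ppp1r15a at −2.26 (SE 0.25), which encodes an eIF2α phosphatase subunit. Eif2s1 was lower with RNase I by 0.97 (SE 0.09). Lists higher with RNase I were nuclear-encoded oxidative phosphorylation (23 up and 6 down of 49, median 0.20, camera adjusted p = 4.1e-04) and lysosome and autophagy (17 up and 2 down of 31, 0.26, 4.1e-04). So were the unfolded protein response (11 up and 2 down of 24, 0.29, 0.018), cholesterol synthesis (12 up and 1 down of 25, 0.27, 0.025) and glycolysis (11 up and 1 down of 21, 0.35, 0.012). These calls were lost with an estimated correlation, at an adjusted p of 0.50, or 0.65 for cholesterol synthesis. With the block the upstream reading frame list was called as well (−0.34, 0.043; 0.359 with an estimated correlation).

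**Figure D4:**
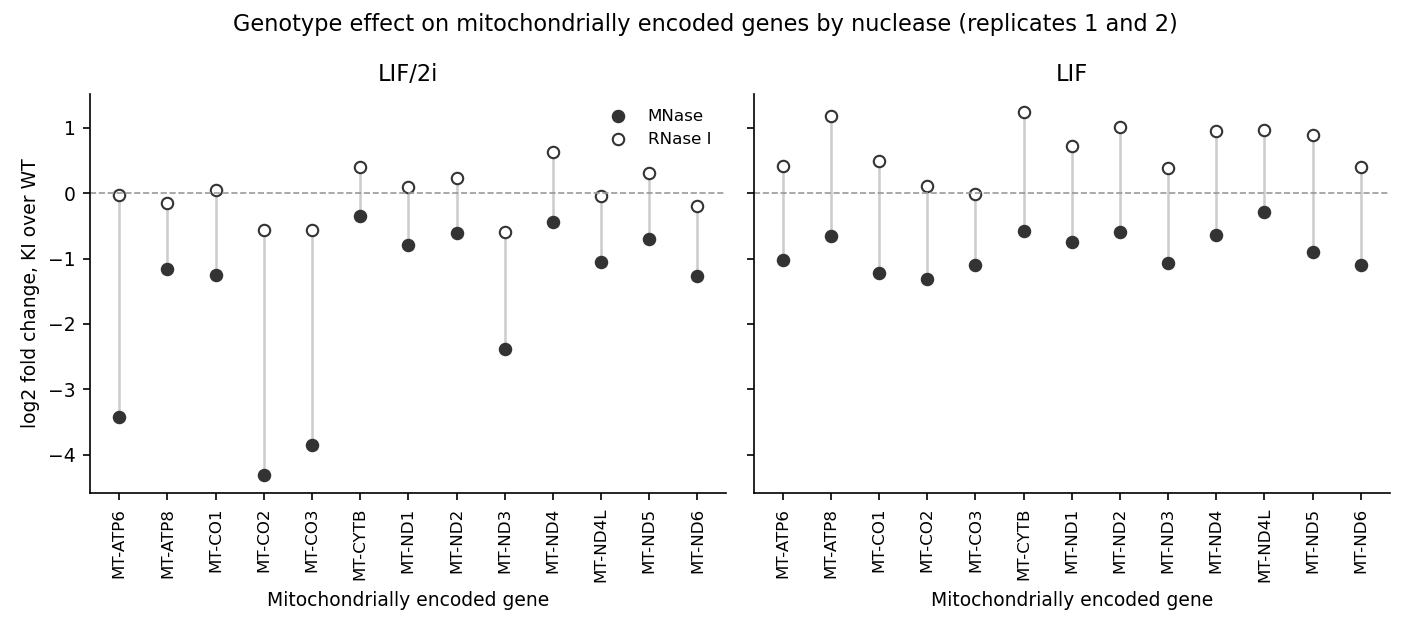
Genotype effect (log2 fold change, KI over WT) of the 13 mitochondrially encoded genes in LIF/2i and LIF, from replicates 1 and 2 of the MNase (filled) and RNase I (open) libraries. A grey line joins the values of each gene, and no errors are drawn. The difference between nucleases had a median of −1.07 in LIF/2i and −1.50 in LIF.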

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

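Tests chosen only after the result was seen were those of a preparation fault and of mixed cells in KI replicate 1, of fewer mitochondrial footprints in KI cells, of RNase I for the stress response, and all splits of the samples.

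A difference between groups was found by the interaction test for 43 genes. The interaction (log2) was 2.81 for MT-CO2, 2.66 for MT-CO3, 2.65 for Lef1, 2.52 for H2ac18, 2.50 for Sox3, 2.35 for HIST1H4M, 2.15 for Abhd8 and 1.76 for Ccdc136. It was −3.75 for Spry4, −3.46 for Lin28a, −3.09 for Rhox9, −3.02 for Rpl7, −2.79 for Cd63, −2.06 for Rplp0, −2.04 for Eif4a3, −1.96 for Ptges, −1.93 for Eras and −1.47 for Gsto1. Lists whose medium effect differed between genotypes by camera at the preset correlation, none of them with an estimated correlation (adjusted p from 0.070 to 0.50), had medians of 0.64 for formative genes, −0.97 for the stress response, −0.40 for upstream reading frames, −0.31 for MEK/ERK targets, −0.21 for ribosomal proteins, −0.17 for other oligopyrimidine tracts, 0.32 for glycolysis, 0.40 for mitochondrially encoded and −0.27 for nuclear-encoded oxidative phosphorylation subunits. The others were −2.17 for the 2-cell-like state (3 members tested), −0.61 for endoderm, −2.04 for trophoblast, −1.57 for fibroblasts, 0.30 for histones and −0.84 for germline genes. Of these, 8 lost the call without single libraries, histones without 8 and glycolysis and germline genes without 5 each. Lists whose genotype effect differed between nucleases, MNase minus RNase I, had medians in LIF/2i of 0.31 for the unfolded protein response, −0.31 for ribosomal proteins, −1.07 for mitochondrially encoded subunits, 0.35 for lysosome, 4.49 for the 2-cell-like state (3 members tested) and −0.52 for histones. With an estimated correlation only lysosome passed (adjusted p = 0.037, but 0.400 with a replicate block), at 0.829 for the first 2 lists and 0.634 for the other 3. In LIF they were 0.27, −0.54, −1.50 and 0.23 for the unfolded protein response, ribosomal proteins, mitochondrially encoded subunits and lysosome, and −0.16 for oligopyrimidine tracts, 0.29 for cholesterol synthesis, 0.20 for S phase and −0.29 for histones. None of these passed with an estimated correlation, the lowest adjusted p being 0.263. The replicate block added G2 and M phase in LIF/2i (0.20, camera adjusted p = 0.028) and fibroblasts in LIF (−0.29, 0.031), neither with an estimated correlation.

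Among the 50 splits for the interaction, 4 gave at least as many genes as the 43, the real one included, and the highest other gave 611, so chance was not excluded by this count. The 3 larger splits were among 7 that exchanged all 3 libraries of 1 medium between genotypes, which brings the genotype effects themselves into the contrast. The others of these 7 gave 1, 0, 0 and 0 genes. All 7 also exchanged 1 or 2 libraries of the other medium, so the exchange alone was not run. Genotype effects may add to the 3 larger counts, whose structure was not tested, so they do not settle what chance gives. None of the 42 drawn without such an exchange gave as many, and these mix genotypes within groups, so the splits leave open whether chance gave the 43. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real splits gave 3250, 1718, 2690 and 2395 genes (1 of 10 splits each), and the highest others gave 18, 0, 0 and 0. For the nuclease, the real split of 4080 genes was the largest of 50 (1 as large, highest other 1186). The other splits put libraries of both nucleases under 1 label, which raises the spread, so they do not settle what chance gives.

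Integrated stress response targets differed between media in WT and had a median near 0 between media in KI. After thinning to equal depth the median interaction was −0.94. Random thinning leaves expected fold changes as they are, so this cannot decide on a cause tied to depth. KI replicate 1 as the whole cause is argued against by a median interaction of −0.90 without it. Preparation of the MNase libraries alone is argued against by −0.77 with RNase I. Open are the difference of depth, a difference of line or clone between genotypes, and a batch that the labels do not give. The design cannot part these from genotype. No phosphorylation was measured here, so its part in the response of WT stays open as well.

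Mitochondrially encoded footprints were lower in KI with MNase. Fewer such footprints in KI cells as a whole would lower them with both nucleases, but the median was −0.024 in LIF/2i and 0.70 in LIF with RNase I. An MNase digestion or preparation that differed between genotypes would give nuclear genes a shared shift in both media. The correlation of that shift between media was 0.138, 0.168 and 0.272 over 3 choices of libraries, against a bound set in advance of over 0.2 for that cause and under 0.05 against it, so this explanation stays open.

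KI replicate 1 stood apart from KI replicates 2 and 3. A fault in single libraries is argued against by the correlation between nucleases of replicate 1 minus replicate 2, at 0.673 and 0.735 in the 2 media. A WT label on the wrong culture is argued against by its position on the axis from WT (0) to KI replicates 2 and 3 (1), at 0.394 and 0.511, outside the WT range of −0.20 to 0.13. WT cells mixed in would place genes between KI and WT, but of 12806 tested genes 1255 (9.80%) were called against both WT and KI replicates 2 and 3 in the same direction, that is beyond both, and 151 in opposite directions, that is between. Replicate 1 of both media was the arm of these tests, with 1 library per medium, and the other genes were not called against both. These libraries shared deviations (residual correlation 0.563), so the arm may stand for 1 sample, and its spread was taken from the other groups. A separate line or clone, or a difference within the KI cells such as loss of the Y chromosome, stays open and was not tested.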

How the results depend on the processing

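Alternatives without KI replicate 1 or KI replicates 2 and 3, the block within genotypes, thinning, the difference between nucleases with and without a block, and MNase replicate 3 alone were chosen after the data were seen.

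The counts of called genes stayed within 1.5 times under RLE, a filter of at least 5 CPM and removal of abundant gene families. So did the 4 counts fitted with the compared groups alone, which left out the interaction and RNase I. Results of named genes, counted per comparison, were unchanged in 95 of 95 cases under RLE and a replicate block. They were unchanged in 94 of 95 with DESeq2 and library totals. A test against a fold of 1.5 gave 408, 82, 909, 820 and 9 genes with MNase in the order of the comparisons, and 6, 0, 820, 110 and 0 with RNase I. DESeq2 gave 218 for the MNase interaction and 272, 196, 827 and 26 with RNase I for both genotype comparisons, the KI media and the interaction. No filter gave 326, 200, 1017 and 29 for these. Both nucleases together gave 1874 for KI against WT in LIF/2i, and RNase I alone gave 28, 14, 1649, 418 and 0. Upper-quartile factors and library totals gave 4 and 6 for RNase I in LIF. The replicate block gave 50 and 27 for the RNase I genotype comparisons, and the block within genotypes 3595 in KI media and 218 for the interaction. Without KI replicate 1 the MNase counts were 4949, 3384 and 437 for the interaction, and without KI replicates 2 and 3 1211 and 1067, which leaves 1 KI library per medium, taken to vary like the WT groups. Of 64 list results this lost 5 calls and gained 8, and thinning lost 7 and gained 4 of 155. Thinning gave 1611, 940, 1407, 1152 and 22. With 1 library left out the ranges were 1574 to 3888, 718 to 2242, 1654 to 3172, 1478 to 2805 and 10 to 148 with MNase, and 0 to 102, 0 to 45, 326 to 2241, 86 to 748 and 0 to 2 with RNase I. They were 3479 to 4135 for the nuclease and 0.465 to 0.519 for the correlation between media. Directions reversed with RNase I for histones in LIF/2i (0.18), ribosomal proteins (0.41) and mitochondrial subunits (0.70) in LIF, and the interactions of HIST1H4M (−0.34), Rpl7 (0.35), ribosomal proteins (0.14) and oligopyrimidine tracts (0.085); the cause was not tested. Of 93 results of named genes, a gene being counted in each comparison that names it, 41 were unchanged with RNase I and 50 lost the call. The unchanged results include those of Eif2s1 that passed with neither nuclease. Of 160 list results, called or not, 48 lost the call with an estimated correlation, 0 gained one and 112 were the same. The unchanged results are mostly lists that passed in neither. Endoderm markers between genotypes in LIF kept their call (camera adjusted p = 0.034 with an estimated correlation). With fry 21 lost the call, 14 gained one and 125 were the same. The replicate block changed no call of the named genes, and among lists it lost WNT targets in WT and trophoblast in KI between media and gained germline genes in LIF/2i between genotypes. Of simulated changes of 2-fold, 38.8% were found at the depth and number of the MNase libraries and 17.9% at those of the RNase I libraries.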

Other observations

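The test of a shift toward the LIF profile was set before its result was seen, and the genes named beside it were chosen after their values were seen.

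Some single genes, picked by hand, differed between genotypes or media. Gdf3, a TGF-beta family ligand, was higher in KI in both media by 0.93 (SE 0.19). Eif2b5, the catalytic subunit of eIF2B, was lower in LIF by 1.13 (SE 0.14) in WT and by 1.13 (SE 0.14) in KI. The germline genes Mael and Ddx4 rose in LIF, Mael from 2.99 ± 1.06 to 30.3 ± 7.79 CPM in WT and from 14.3 ± 7.80 to 31.7 ± 5.77 in KI, while Dazl fell by 1.80 and 1.44. The p53 target Cdkn1a fell in LIF by 2.02 in WT and 1.88 in KI. The imprinted gene Peg3 rose in LIF by 1.29 (SE 0.23) and 1.46 (SE 0.23).

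KI cells in LIF/2i may lie toward the LIF profile, as a hypothesis from the levels of Lin28a, Spry4 and Tagln in KI in LIF/2i. The test correlated, across genes, each KI MNase library in LIF/2i minus WT replicate 3 with the WT medium effect in RNase I replicates 1 and 2. The correlation was 0.131 for KI replicate 3, 0.138 for replicate 2 and −0.048 for replicate 1, against a bound set in advance of over 0.1 for replicate 3, which was met. The replicates differed in sign, and the same measure for KI in LIF was −0.046, 0.074 and 0.111 for replicates 1, 2 and 3, so the shift was not particular to LIF/2i. On the first principal component KI replicates 1, 2 and 3 in LIF/2i lay at −39.1, −13.5 and −16.2, nearer the LIF libraries than WT at −69.7, −63.8 and −44.6. WT replicate 3, the reference of the test, was the WT library nearest LIF. The hypothesis stays open.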
